A study of Homo sapiens with 16 samples.

How the data were processed

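Chromatin immunoprecipitation sequencing (ChIP-seq) was done in HCT116, an established human colon cancer cell line, with antibodies against ARID1A, H3K9me3, TRIM28 and SETDB1. ARID1A is a subunit of the SWI/SNF chromatin remodeller. TRIM28 is a corepressor that recruits SETDB1, an enzyme that methylates histone H3 at lysine 9, and H3K9me3 is the mark found in heterochromatin. The 16 samples fall into 3 cell states by their titles: cells with no shRNA named in their label (called unmodified here), shCtrl cells and shARID1A cells. Titles with CTR were read as the shCtrl cells that the series' design text names. Each group of cell state and antibody has 1 library. Peak lists of 10 precipitated libraries were used, each called against 2 controls (input and IgG), which gave 20 lists. The 6 input and IgG samples have no list of their own, and ARID1A ChIP in shARID1A cells was not analysed here.

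FastQC 0.11.9, Bowtie2 2.2.5, MACS2 2.2.7.1, deepTools 3.5.1 and ChIPseeker (version not given in the sources used here) are named in the submitters' processing notes, with the builds GRCh38 and hg38. Options of these tools are not given in the sources used here. Peaks were called per library by the authors, and the name of each list gives its control, which no label states. Lists of a cell state were taken to share 1 input and 1 IgG library, so a chance dip of that control can give peaks to several of them, and shifted positions do not allow for this. The deposited fold enrichment of each peak is a ratio of the pileup at the summit to the local background, and it is the authors' value. The deposited −log10 p and −log10 q of each peak come from the same peak call. Each list reached down to an unadjusted p of about 0.05, as seen in the deposited values, and q was 1 (a −log10 q of 0) for between 8.02% and 99.9% of the peaks of a list. Fold enrichment was used here to rank and describe peaks within a list. For H3K9me3 and TRIM28, the antibody product named in the protocol differs from the product named in the sample characteristics, so the antibody used is not settled here.

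Depth was not stated. From each peak's fold and p, the pileup and background were recovered as whole fragments times a scale, with a tolerance of 0.0005 in −log10 p, for at least 99% of 400 sampled peaks per list, drawn from peaks with a fold below 4. In 7 lists the precipitated library was not scaled, and in 13 it was scaled down to its control. Against input the scales for H3K9me3, TRIM28 and SETDB1 were 0.75, 0.77 and 0.74 in shCtrl and 0.96, 1 and 0.97 in shARID1A. The most common background was 8.46 fragments per kb in unmodified TRIM28, 4.45 in shCtrl TRIM28 and 5.59 in shARID1A TRIM28. Peaks of these states were thus called at unlike depth, and peak numbers were not adjusted for it. The median summit of the sampled peaks held 5 to 12 fragments. On simulated peaks, planted scales of 1, 0.85 and 0.6 came back as 1, 0.85 and 0.6. Sequencing totals were not derived.

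Peaks on chromosomes 1 to 22 and X were kept. The main list was the one called against input at the authors' threshold. An overlap of at least 1 bp counted as shared. Peaks were narrow, with a median width of 218 to 345 bp per list. A wider region in which lists placed peaks at different positions thus counted as not shared. Expected overlap came from 1000 circular shifts of the first list within each chromosome (200 for alternatives), and the fold is the observed share over the median of the shifts. No genome sequence was used, so shifts ran over 10000 bp windows touched by any list (2.67 Gb) in place of assembled sequence. This departs from the plan. Shares have exact Clopper-Pearson 95% intervals, differences between separate sets of peaks Newcombe intervals, and differences on the same peaks an interval from the discordant peaks. All cover counting error only.

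Gene positions and names came from a RefSeq table of GRCh38.p14, which carries no strand or exons, so start sites, exons, introns and repeats were not used here. A gene had a peak if one overlapped its body extended by 1000 bp. For each of 14 gene lists the share of protein-coding members with a peak was placed among 10000 random lists matched on gene length decile. This percentile describes a library and is no test between conditions. Genes were named by this rule. For H3K9me3, TRIM28 and SETDB1, lost regions were shCtrl peaks among the 10000 with the highest −log10 q (ties by p, then fold), in both control lists of shCtrl and in neither list of shARID1A. Gained regions were the same with the states exchanged. The 12 lost and 12 gained regions with the highest fold that lie in a protein-coding or lncRNA gene gave the names, with 1 region per gene. For ARID1A, the 12 genes of shCtrl peaks with the highest fold that overlap TRIM28 and H3K9me3 peaks in both control lists were named, and from each gene list the 3 members with the highest fold in its leading shCtrl library, the one with the highest ratio to random lists. ARID1A, TRIM28 and SETDB1 were always named. A SETDB1 region that the rule names is not reported here. Samples, comparisons, gene lists, naming rule and the first group of alternatives below were set before the data were examined.

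The first alternatives were the IgG lists, peaks in both controls, −log10 q of at least 5, the top 10000 peaks, 50% overlap of the shorter interval, merging within 1000 bp and deciles of fold. A q of at most 0.05, ARID1A sites of unmodified cells and pairs of lists with different controls (the first against input and the second against IgG, and the reverse) were added after seeing the data. Under an alternative, a share of peaks was given only for lists of at least 20 peaks. The overlap step was tested on simulated lists of 20000 peaks: planted shares of 5% and 20% came back as 5.17% and 20.0%, and a planted share of 0 as 0.0809%. For retention differences, 95.1% of 1000 simulated intervals held the planted difference, and 4.8% of 1000 unrelated gene lists fell past the 2.5 or 97.5 percentile. Genes of these simulated lists were drawn at random and given peaks independently of each other. The simulation thus does not cover lists whose members lie in clusters, and the percentiles do not allow for clustering. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.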

Results

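ARID1A, H3K9me3, TRIM28 and SETDB1 were mapped by ChIP-seq in HCT116 cells, to ask how ARID1A relates to heterochromatin. Unmodified cells had ARID1A, H3K9me3 and TRIM28 libraries, shCtrl cells all 4, and shARID1A cells H3K9me3, TRIM28 and SETDB1. Each group held 1 library, so no difference between cell states has a replicate check, and intervals cover counting error only. Input lists held from 11374 peaks (unmodified H3K9me3) to 203714 (shARID1A TRIM28). At a q of at most 0.05, called strong below, 15 peaks were left in unmodified H3K9me3, 67 in unmodified TRIM28, 43 in shCtrl ARID1A and 25 in shCtrl TRIM28, against 37702 in shCtrl SETDB1. Loss of ARID1A was not measured by ARID1A ChIP here, so libraries are named by their labels. Overlaps between libraries of different antibodies, given at the end, leave the labels of shCtrl H3K9me3 and shCtrl SETDB1 open.

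The gene ARID1A itself, on chromosome 1 from 26696015 to 26782104 (hg38), carried strong SETDB1 and TRIM28 peaks in shARID1A cells. The library labelled shARID1A SETDB1 had 10 strong peaks there against input, the highest at 26696374 to 26697576 with a fold enrichment of 24.0. The library labelled shARID1A TRIM28 had 6 strong peaks, the highest at 26696413 to 26697570 with a fold of 10.5, and all 6 lay at strong SETDB1 peaks. Against IgG the numbers were 11 and 7. The H3K9me3 library of these cells had 1 strong peak in the gene, at 26744264 to 26744534 with a fold of 4.81, at none of the strong SETDB1 sites of these cells. In shCtrl cells TRIM28 had 0 strong peaks in ARID1A and SETDB1 had 1 against input, at 26744065 to 26744443, which overlapped that H3K9me3 peak. The place of the tallest peaks was also occupied in shCtrl ARID1A, by a peak at 26696398 to 26697440 against input (fold 5.16, not strong) and a strong one at 26696394 to 26697451 against IgG (fold 5.63). No strong peak was listed against input in the TRIM28 gene except 1 of shCtrl SETDB1 with a fold of 3.48, or in the SETDB1 gene except 1 of shCtrl SETDB1 with a fold of 6.84.

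**Figure D1:**
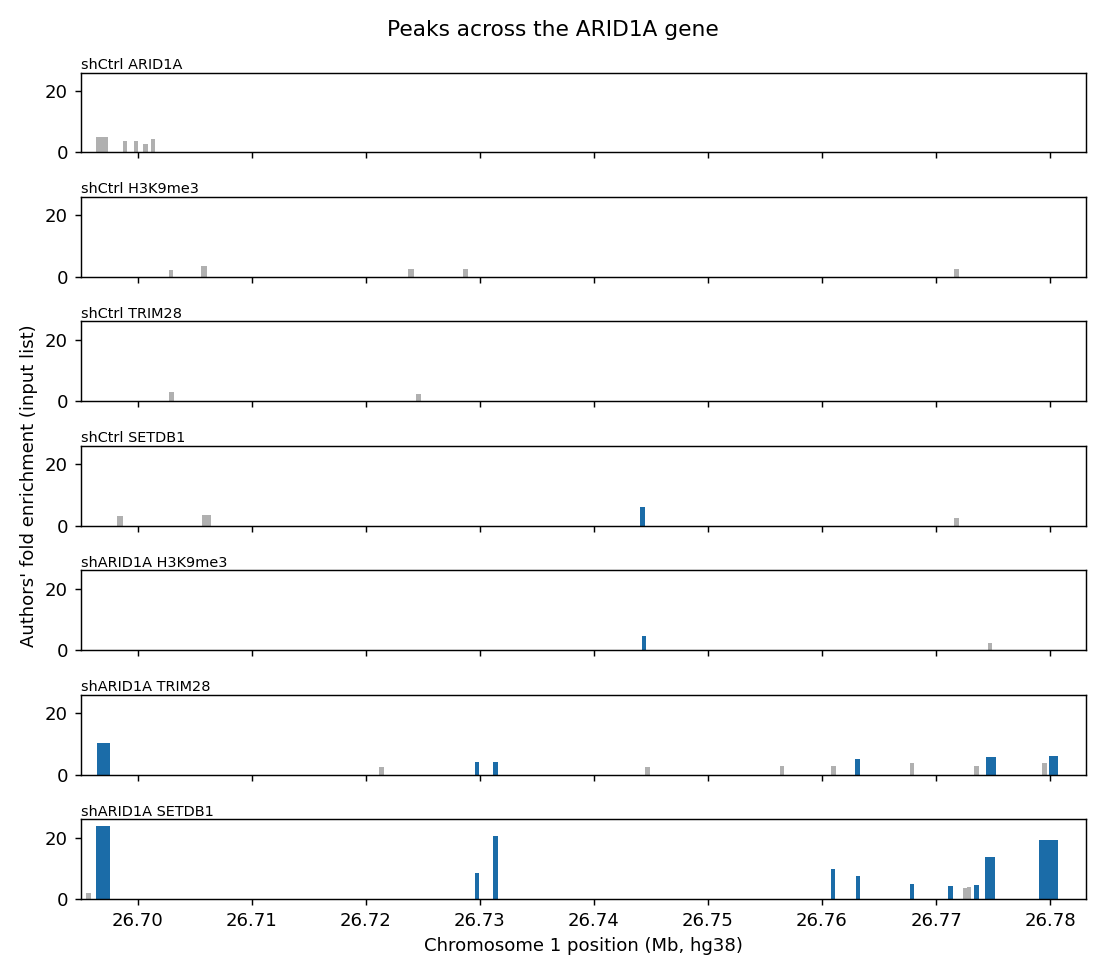
Peaks of the input lists across the ARID1A gene in the 7 shCtrl and shARID1A libraries, with chromosome 1 position in Mb (hg38) on the x axis and the authors' fold enrichment on the y axis; blue bars are peaks with a q of at most 0.05, grey bars the other peaks, and narrow peaks are widened to be visible. The tallest bars, 24.0 in shARID1A SETDB1 and 10.5 in shARID1A TRIM28, stand at the same place.

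H3K9me3 in the input lists had 92063 peaks in shCtrl and 56886 in shARID1A cells, a log2 ratio of -0.69, covering 27.6 Mb at a mean fold of 2.89 and 16.2 Mb at 3.44. The direction turned with the control and the threshold: against IgG there were 226527 and 270687 peaks, and 6833 and 12115 strong peaks against input. Of the shCtrl peaks, 3.65% (95% interval 3.53% to 3.77%) were found again in shARID1A, 2.81 times the share at shifted positions. The median peak was 247 bp wide in shCtrl and 252 bp in shARID1A, so a low share does not show that wider regions differed. Between unmodified and shCtrl cells, with no knockdown, 5.68% (5.26% to 6.12%) of H3K9me3 peaks were found again, 2.24 times the shifted share. These libraries also differed in depth and peak width, so this share does not measure repeatability alone. Against input the most common background was 8.47 fragments per kb in unmodified and 4.44 in shCtrl H3K9me3, and the narrowest peak 253 and 209 bp. The second list was longer here (92063 peaks against 56886), and the share was higher where the fold was lower. Against IgG the order of the shares turned, with 13.0% from shCtrl to shARID1A and 6.16% from unmodified to shCtrl cells, and 21.5% and 4.67% among strong peaks of those lists. It also turned with both controls required and among the top 10000 peaks of each list (2.41% and 1.06%), but not with 50% overlap (2.83% and 3.89%). Of the top 10000 shCtrl peaks in both control lists 46.8% counted as lost, and of those of shARID1A 83.6% as gained, so either was common. Lost regions lay in GIT2 (fold 13.5), MAPKAP1 (13.4), CRADD (13.0), LARP1B (12.6), NSMCE2 (12.5), PRRX1, MTFR1, MET (11.7), TES, TEAD1 (11.5), VTI1A and TANK-AS1. MET encodes a receptor tyrosine kinase and TEAD1 a transcription factor of the Hippo pathway. All 12 of these regions also held a shCtrl SETDB1 peak, and 11 held a peak of the library labelled unmodified ARID1A. Of the same 12 regions 0 held a peak of unmodified H3K9me3, whose input list was short, with 11374 peaks. A wrong label or mixed chromatin in the library labelled shCtrl H3K9me3 is left open below, so these regions may not be lost H3K9me3. Gained regions lay in TP53TG1 (26.4), TMEM182 (20.3), DISP3 (19.7), GABBR2 (18.8), NCR3LG1, AKR1C8, SPESP1-NOX5, EXOC6, FGD5, FAM163B, SEPTIN14 and RSRC1. All 12 gained regions held a shCtrl SETDB1 peak, 10 held a shARID1A SETDB1 peak and 0 held an unmodified H3K9me3 peak.

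TRIM28 peaks against input numbered 70447 in shCtrl and 203714 in shARID1A cells, a log2 ratio of 1.53, covering 18.1 Mb at a mean fold of 2.72 and 56.3 Mb at 2.55. Against IgG the numbers lay closer, 264115 and 281182. Strong peaks numbered 25 and 2119. None of these numbers was adjusted for the unlike depth of the lists. Of the shCtrl peaks 5.57% (5.40% to 5.74%) were found again, 1.31 times the shifted share. From unmodified to shCtrl cells the share was 4.68% (4.45% to 4.91%), 2.51 times the shifted share. These libraries differed in depth as well, with a most common background of 8.46 fragments per kb in unmodified and 4.45 in shCtrl TRIM28. Of the 25 strong shCtrl peaks 15 met a strong shARID1A peak, 60% (38.7% to 78.9%), and 9.53% of 598 did so against IgG. The highest gained region lay in ARID1A, followed by RHOU (7.32), UGT1A8 (7.06), NDEL1, DSN1, DPY19L1, DCP1B, SAFB2, KLHL6, NBPF20, TAX1BP3 and TBX2. Of the top 10000 shCtrl peaks in both control lists 88.2% counted as lost, and of those of shARID1A 88.4% as gained. Lost regions were weak: 5 of all 7127, and 3 of the 12 named, had a q of at most 0.05. The named ones had folds of 4.76 to 5.34 and lay in TMCC2, TNIK, KIAA0319L, BRINP3, GPHN, CACNG1, PHRF1, NECAB1, TOR1AIP2, HEATR6, NBPF14 and CALCRL-AS1.

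SETDB1 had 37702 strong peaks in shCtrl and 1363 in shARID1A cells against input. At the authors' threshold 79404 and 39245 peaks were listed against input, a log2 ratio of -1.02, covering 30.5 Mb at a mean fold of 3.98 and 10.5 Mb at 3.03. Against IgG the direction turned at that threshold, with 114369 and 276586 peaks, but not among strong peaks, with 55343 and 6838. Of the shCtrl peaks 4.8% (4.66% to 4.96%) were found again, 4.84 times the shifted share, in a shARID1A list that was shorter, and 24.3% against IgG. In reverse 9.75% of shARID1A peaks lay at a shCtrl peak, and 42.9% of the strong ones at a strong shCtrl peak. Of the top 10000 shCtrl peaks in both control lists 49.4% counted as lost, and of those of shARID1A 76.9% as gained. Lost regions lay in TPST1 (25.6), DEGS2 (22.7), PIWIL4 (22.6), SRGAP2B, MKLN1, FAM163B, TMEM182, RNLS, LINC01572, LPP, ATF1 and HDAC9 (18.0), a histone deacetylase gene. All 12 of these held a peak of the library labelled shARID1A H3K9me3. Gained regions included those in C1orf159 (24.3), ARID1A (24.0), UCKL1 (23.7), IFRD2 (22.9), PTDSS2, TCEA2, TBX6, PEMT, ST3GAL2, PHF13 and TMEM11, and 6 of the 12 gained regions held a shCtrl ARID1A peak.

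**Figure D2:**
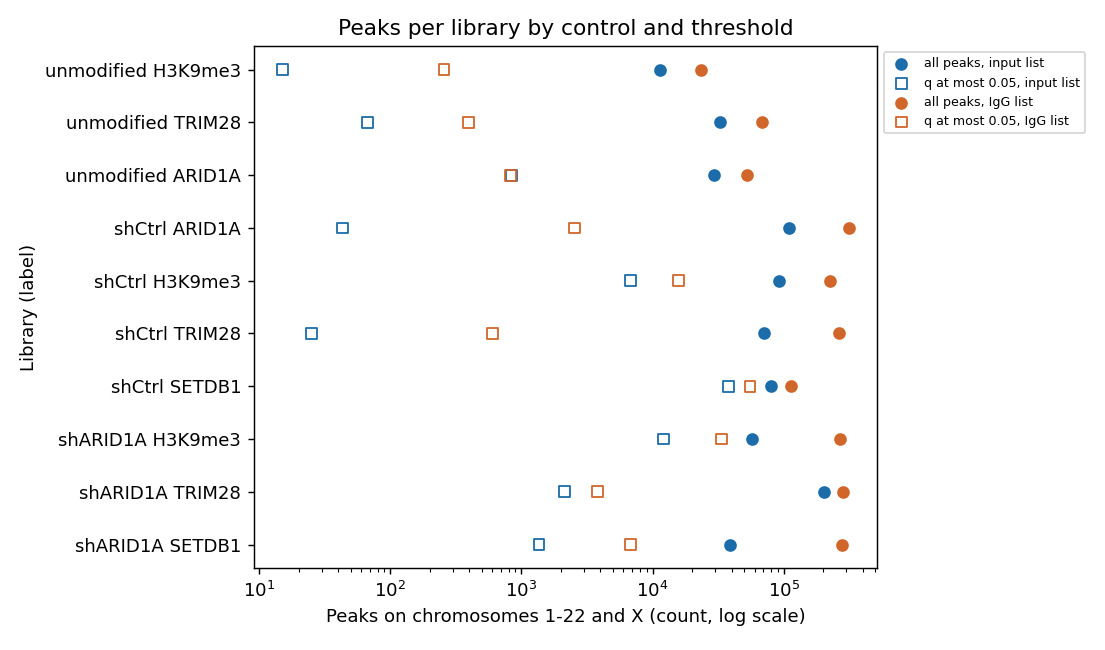
Number of peaks per library on a log axis, for 10 libraries, the input (blue) and IgG (orange) control and the authors' threshold (filled circles) or a q of at most 0.05 (open squares). Strong peaks against input range from 15 in unmodified H3K9me3 to 37702 in shCtrl SETDB1.

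ARID1A peaks overlapped peaks of the other 3 antibodies in the same cells, by a margin that depended on the control. Against input, in shCtrl cells 10.1% (9.89% to 10.3%) of 108926 ARID1A peaks met H3K9me3, 4.43 times the shifted share, 5.19% met TRIM28 (3.15 times) and 11.3% met SETDB1 (5.37 times), and 0 of 1000 shifts reached any of these shares. In unmodified cells the folds were 5.43 for H3K9me3 and 5.28 for TRIM28. Lists of a cell state were taken to share their control library, so part of the excess over shifted positions may come from that control. With ARID1A called against input and the other list against IgG, the shCtrl folds were 1.75 for H3K9me3, 1.11 for TRIM28 and 3.37 for SETDB1, and the unmodified ones 0.868 for H3K9me3, within the spread of the shifts, and 1.22 for TRIM28. With ARID1A against IgG and the other list against input they were 2.05, 1.36 and 3.11 in shCtrl and 2.01 and 2.36 in unmodified cells. Peaks with ARID1A, TRIM28 and H3K9me3 in both control lists numbered 340, and 0 of them were strong for ARID1A. Those with the highest ARID1A fold lay in EPB41L2 (4.74), RCL1 (4.74), DDX10 (4.74), ZBTB20 (4.66), OXR1, AP3S1, RIMS2, BCAR3, MBNL1, PHLDB2, ZFPM2 and JPH1 (4.06). ZBTB20 encodes a zinc finger repressor and DDX10 an RNA helicase.

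TRIM28, SETDB1 and H3K9me3 also overlapped each other in both states, again between lists that share a control. In shCtrl cells 22.3% of SETDB1 peaks met H3K9me3, 9.08 times the shifted share, and in shARID1A cells 11.2%, 9.20 times. TRIM28 with SETDB1 gave folds of 3.75 in shCtrl and 4.14 in shARID1A cells, and TRIM28 with H3K9me3 gave 3.54 and 4.39. With the second list of each pair against IgG, the folds were 4.62 and 2.79 for SETDB1 with H3K9me3, 2.27 and 1.45 for TRIM28 with SETDB1, and 1.39 and 1.68 for TRIM28 with H3K9me3. With the first list against IgG they were 6.22 and 2.63, 1.83 and 2.39, and 1.33 and 2.56. At ARID1A sites of shCtrl cells, H3K9me3 was present at 10.1% in shCtrl and 1.95% in shARID1A, a difference of -8.12 percentage points (-8.31 to -7.93). This difference rests on the library labelled shCtrl H3K9me3, whose label is left open below. SETDB1 went from 11.3% to 2.15%, a difference of -9.14 (-9.35 to -8.94), and TRIM28 from 5.19% to 5.77%, a difference of 0.577 (0.386 to 0.767). Over shifted positions the fold was 4.43 in shCtrl and 1.52 in shARID1A for H3K9me3, 5.37 and 2.45 for SETDB1, and 3.15 and 1.29 for TRIM28, so that for TRIM28 the fold was lower where the share was higher. Only the shCtrl lists shared a control with the ARID1A list. With ARID1A against input and the other lists against IgG, the differences were 1.35 for H3K9me3, 4.98 for SETDB1 and 6.33 for TRIM28, and with ARID1A against IgG and the others against input -2.12, -4.52 and 3.93. For H3K9me3 the folds lay close in the first of these settings (1.75 in shCtrl and 1.69 in shARID1A), and were 2.05 and 1.78 in the reverse. For SETDB1 they were lower in shARID1A in both (3.37 and 2.33, 3.11 and 2.28), whereas for TRIM28 they were 1.11 and 2.01, and 1.36 and 1.35. With all lists against IgG the SETDB1 difference was 2.91 and the H3K9me3 difference -1.04, but -18.8 (-20.8 to -16.8) and 11.5 (9.66 to 13.3) among strong peaks of those lists, and at ARID1A sites of unmodified cells the TRIM28 difference was -0.456 (-0.803 to -0.110).

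H3K9me3 peaks at ARID1A sites were found again in shARID1A cells slightly more often than those elsewhere, 5.95% of 10849 against 3.34% of 81214, a difference of 2.61 percentage points (2.16 to 3.08). Within deciles of fold it was 1.08, and for strong shCtrl peaks looked up in the whole shARID1A list 0.509 (-1.34 to 2.45), where none was detectable. For TRIM28 the difference was -0.160 (-0.749 to 0.485), and 0.913 (0.252 to 1.63) after merging within 1 kb. For SETDB1 it was -0.546 (-0.934 to -0.133), and with other settings of the input lists it ran from -6.42 (-7.85 to -4.43) among the top 10000 peaks to 0.359 (-0.0994 to 0.842) after merging, with -0.188 (-0.652 to 0.319) where both controls were required. Against IgG the differences were 14.4 for H3K9me3, 5.35 for TRIM28 and 16.8 for SETDB1.

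Zinc finger (ZNF) genes, clusters of which are a known site of H3K9me3, parted the H3K9me3 libraries. In unmodified cells 34 of 246 ZNF genes on chromosome 19 had an H3K9me3 peak, 1.72 times random lists (percentile 99.9), and 64 of 263 ZNF genes elsewhere, 2.0 times. In the library labelled shCtrl H3K9me3 28 of 246 on chromosome 19 had one, 0.270 times, and in shARID1A H3K9me3 113 of 246, 1.08 times (percentile 86.8). The shARID1A ratio became 0.920 (percentile 0) against IgG, but 1.48 (percentile 99.2) among the top 10000 peaks and 1.37 (percentile 98.2) among strong ones. The library labelled unmodified ARID1A had 3 of 246, 0.0638 times. Against IgG shCtrl H3K9me3 had 155 of 246 (0.761 times) and unmodified ARID1A 28 (0.285 times). In shCtrl SETDB1, the shCtrl library with the highest ratio for this list, the highest folds were in ZNF761 (15.4), ZNF333 (13.8) and ZNF225 (12.3).

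Replication-dependent histone genes had a shCtrl SETDB1 peak in 49 of 69 cases, 3.48 times random lists, with H2BC4 and H2AC6 (10.4, 1 shared region) and H2BC15 (9.43) at the top. Ribosomal protein genes had one in 69 of 83 cases, 2.48 times, led by RPL27 (14.4), RPL35A (10.3) and RPL24 (9.51). Against IgG the ratios were 2.39 for histone and 1.89 for ribosomal protein genes. The excess against input was not limited to SETDB1. For histone and ribosomal protein genes the ratios were 1.86 and 1.80 in shCtrl ARID1A, and 1.93 and 2.30 in shARID1A H3K9me3. They were 2.45 and 2.92 in unmodified TRIM28. Lower ratios were found in shCtrl TRIM28 (1.61 and 1.25, percentiles 90.1 and 80.0), shCtrl H3K9me3 (1.10 and 0.938) and unmodified H3K9me3 (0 and 1.54). In shARID1A SETDB1 these lists had 12 of 69 (1.40 times, percentile 89.4) and 25 of 83 (1.52 times, percentile 98.8), and against IgG 47 of 69 (1.58 times) and 76 of 83 (1.40 times), close to the 51 and 77 of shCtrl SETDB1. Among strong peaks against input they had 0 of 69 and 4 of 83, from 1363 peaks. Strong shCtrl SETDB1 peaks gave 46 and 50, from 37702 peaks. Among p53 targets 22 of 25 had a shCtrl SETDB1 peak, 1.53 times, led by SUSD6 (11.9), BTG2 (5.79) and TNFRSF10B (5.54). With strong peaks 18 of 25 had one (1.79 times, percentile 99.96), and with the top 10000 peaks 6 (1.62 times, percentile 89.4). In shARID1A SETDB1 18 of 25 had a peak, 1.80 times, and in unmodified ARID1A 11, 2.08 times. Against IgG all 25 had one in shARID1A SETDB1, so its ratio of 1.18 could be no higher. All 25 also had one against IgG in shCtrl ARID1A, shARID1A H3K9me3 and shARID1A TRIM28. Among strong shARID1A SETDB1 peaks the ratio was 1.06 (1 of 25, percentile 56.9), and among the top 10000 it was 1.42 (percentile 83.0). Interferon and RNA-sensing genes had a shCtrl H3K9me3 peak in 16 of 33 cases, 1.42 times (percentile 97.0), which became 1.10 times against IgG and 0.858 among the top 10000 peaks (2 of 33), with 1 of 33 among strong peaks, and a shCtrl SETDB1 peak in 21, 1.28 times. Highest in shCtrl H3K9me3 were EIF2AK2 (3.69), IFIT3 (3.35) and OAS1 (3.25). Of the genes for heterochromatin writers and readers 21 of 28 had a shCtrl SETDB1 peak, 1.03 times, with ATF7IP (19.9), SMCHD1 (11.2) and CBX5 (9.91) highest. Of the SWI/SNF subunits 18 of 26 had a shCtrl ARID1A peak, 1.02 times, with ARID1A (5.16), SMARCE1 (4.32) and ARID1B (4.32) highest. Olfactory receptor genes had a shCtrl SETDB1 peak in 39 of 392 cases, 0.329 times, and a shCtrl TRIM28 peak in 47, 1.02 times (0.806 against IgG), with OR4F16, OR51B5 and OR51B2 highest. The germline list of MAGE, GAGE, PAGE, XAGE and SSX genes had a shCtrl TRIM28 peak in 6 of 58 cases (0.651 times, percentile 10.3), with SSX2IP, MAGEA9B and GAGE12J highest. SSX2IP entered by its symbol and is not an SSX family gene.

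Imprinted genes had a shCtrl H3K9me3 peak in 12 of 28 cases (0.926 times), led by GRB10, INPP5F and DIRAS3. Intestinal and WNT genes had a shCtrl ARID1A peak in 16 of 31 (0.942 times), led by TCF7L2, RNF43 and LEF1, whereas unmodified ARID1A had 15 of 31 (1.75 times, percentile 99.8, and 1.46 against IgG). With shCtrl TRIM28 the clustered protocadherins had 37 of 53 (1.19 times), led by PCDHB8, PCDHB14 and PCDHAC2, from 15 peaks, since members of a cluster overlap. The ratio was 1.07 (percentile 92.3) against IgG and 0.138 (2 of 53) among the top 10000 peaks. ZNF genes on other chromosomes had 126 of 263 (1.18 times, percentile 99.6, and 1.04 times, percentile 94.1, against IgG), led by ZNF330, ZNF860 and ZNF385B. Of the endogenous retroviral envelope genes 3 of 10 had a shCtrl TRIM28 peak (1.75 times, percentile 84.9, and 0.993 times against IgG): ERVK3-1, ERV3-1-ZNF117 and ERVFRD-1.

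By position, 50.2% (49.9% to 50.6%) of shCtrl H3K9me3 peaks and 39.7% (39.3% to 40.1%) of shARID1A H3K9me3 peaks lay in protein-coding genes, which made up 44.6% of the sequence searched. Against IgG the shARID1A share was 45.1%, above that level.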

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

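The limit on q was chosen after seeing the data. Peaks on sequences outside the assembled chromosomes took no part in the comparisons, yet some had a q of at most 0.05. Against input there were 390 in shCtrl SETDB1, 160 in shARID1A TRIM28, 151 in shARID1A H3K9me3, 78 in shARID1A SETDB1 and 50 in shCtrl H3K9me3. Each is above the 3 counts that a count of 0 allows, as were 27 in shCtrl TRIM28, 11 in unmodified H3K9me3, 9 in unmodified TRIM28 and 9 in shCtrl ARID1A. No explanation was tested.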

How the results depend on the processing

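The alternatives with a q limit of 0.05, with ARID1A sites of unmodified cells and with lists of different controls were chosen after seeing the data. Of 99 alternative values of the 11 overlap folds among ARID1A, H3K9me3, TRIM28 and SETDB1, 98 stayed above shifted positions, up to 184. The value of 184 came from strong TRIM28 with strong SETDB1 peaks in shARID1A, 8.68% against a shifted share of only 0.0472%. The exception was ARID1A (input) with H3K9me3 (IgG) in unmodified cells, and with ARID1A against IgG and H3K9me3 against input the fold was 2.01. Folds of lists of different controls ran from 0.868 to 6.22. No ratio for ZNF genes was given where random lists held on average fewer than 3 genes with a peak. A fold could not be given where the median of the shifted positions was 0, and such alternatives are not among the 99. Some of them had no overlap: 0 of 43 strong shCtrl ARID1A peaks met a strong TRIM28 peak. With −log10 q of at least 5, 0 of 52 unmodified ARID1A peaks met H3K9me3 or TRIM28. Others did overlap, such as 12 of the 43 with strong SETDB1 peaks. Shares, differences and peak numbers moved with the control and the threshold. The direction of the H3K9me3 and SETDB1 peak number ratios turned with the control at the authors' threshold, and that of H3K9me3 with the threshold as well. Reversed values were found for peak numbers, for occupancy of ARID1A sites, for retention of SETDB1 peaks, for ZNF genes and for 1 overlap fold. The cause was not tested. Alternatives that need transcription start sites (distal peaks, promoter windows of 1 kb and 3 kb) and the shares in exons, repeats and satellites were not run. The top lists have fixed length, so they give no peak number ratio. No paired analysis was possible because each group holds 1 library and the result comes from no test. Summits of sampled peaks rested on a median of 5 to 12 fragments, which limits what weak peaks can show. ARID1A loss was not measured by ARID1A ChIP here.

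Against the IgG control, the log2 ratio of peak numbers was 0.26 for H3K9me3, 0.090 for TRIM28 and 1.27 for SETDB1. With −log10 q of at least 5, the log2 ratio of peak numbers was 0.62 for H3K9me3, 4.22 for TRIM28 and -4.86 for SETDB1. At q of at most 0.05, the log2 ratio of peak numbers was 0.83 for H3K9me3, 6.41 for TRIM28 and -4.79 for SETDB1. In IgG lists at q of at most 0.05, the log2 ratio of peak numbers was 1.09 for H3K9me3, 2.66 for TRIM28 and -3.02 for SETDB1. Against the IgG control, the percentage of peaks found again was 6.16 for H3K9me3 from unmodified to shCtrl, 7.89 for TRIM28 from unmodified to shCtrl, 17.2 for ARID1A from unmodified to shCtrl, 13 for H3K9me3 from shCtrl to shARID1A, 7.23 for TRIM28 from shCtrl to shARID1A and 24.3 for SETDB1 from shCtrl to shARID1A. With both controls required, the percentage of peaks found again was 1.97 for H3K9me3 from unmodified to shCtrl, 3.08 for TRIM28 from unmodified to shCtrl, 11.1 for ARID1A from unmodified to shCtrl, 4.32 for H3K9me3 from shCtrl to shARID1A, 3.13 for TRIM28 from shCtrl to shARID1A and 4.23 for SETDB1 from shCtrl to shARID1A. With −log10 q of at least 5, the percentage of peaks found again was 0 for ARID1A from unmodified to shCtrl, 0.443 for H3K9me3 from shCtrl to shARID1A and 1.16 for SETDB1 from shCtrl to shARID1A. Among each list's top 10000, the percentage of peaks found again was 1.06 for H3K9me3 from unmodified to shCtrl, 1.08 for TRIM28 from unmodified to shCtrl, 4.59 for ARID1A from unmodified to shCtrl, 2.41 for H3K9me3 from shCtrl to shARID1A, 0.8 for TRIM28 from shCtrl to shARID1A and 9.95 for SETDB1 from shCtrl to shARID1A. With 50% overlap of intervals, the percentage of peaks found again was 3.89 for H3K9me3 from unmodified to shCtrl, 3.06 for TRIM28 from unmodified to shCtrl, 9.38 for ARID1A from unmodified to shCtrl, 2.83 for H3K9me3 from shCtrl to shARID1A, 3.44 for TRIM28 from shCtrl to shARID1A and 3.96 for SETDB1 from shCtrl to shARID1A. After merging within 1 kb, the percentage of peaks found again was 4.97 for TRIM28 from unmodified to shCtrl, 14.7 for ARID1A from unmodified to shCtrl, 4.08 for H3K9me3 from shCtrl to shARID1A, 6.3 for TRIM28 from shCtrl to shARID1A and 5.56 for SETDB1 from shCtrl to shARID1A. At q of at most 0.05, the percentage of peaks found again was 5.97 for TRIM28 from unmodified to shCtrl, 0.24 for ARID1A from unmodified to shCtrl, 4.3 for H3K9me3 from shCtrl to shARID1A, 60 for TRIM28 from shCtrl to shARID1A and 1.56 for SETDB1 from shCtrl to shARID1A. In IgG lists at q of at most 0.05, the percentage of peaks found again was 4.67 for H3K9me3 from unmodified to shCtrl, 11.1 for TRIM28 from unmodified to shCtrl, 3.28 for ARID1A from unmodified to shCtrl, 21.5 for H3K9me3 from shCtrl to shARID1A, 9.53 for TRIM28 from shCtrl to shARID1A and 4.65 for SETDB1 from shCtrl to shARID1A. With the q limit on the first list alone, the percentage of peaks found again was 14.9 for TRIM28 from unmodified to shCtrl, 44.8 for ARID1A from unmodified to shCtrl, 15.1 for H3K9me3 from shCtrl to shARID1A, 76 for TRIM28 from shCtrl to shARID1A and 7.65 for SETDB1 from shCtrl to shARID1A. Against the IgG control, the change at ARID1A sites, in percentage points, was -1.04 for H3K9me3, 1.63 for TRIM28 and 2.91 for SETDB1. With both controls required, the change at ARID1A sites, in percentage points, was -4.92 for H3K9me3 and -7.21 for SETDB1. Among each list's top 10000, the change at ARID1A sites, in percentage points, was -4.34 for H3K9me3, -0.27 for TRIM28 and -4.39 for SETDB1. With 50% overlap of intervals, the change at ARID1A sites, in percentage points, was -5.6 for H3K9me3, 0.17 for TRIM28 and -6.55 for SETDB1. After merging within 1 kb, the change at ARID1A sites, in percentage points, was -8.92 for H3K9me3, 0.912 for TRIM28 and -9.65 for SETDB1. At q of at most 0.05, the change at ARID1A sites, in percentage points, was 4.65 for H3K9me3, 23.3 for TRIM28 and -6.98 for SETDB1. In IgG lists at q of at most 0.05, the change at ARID1A sites, in percentage points, was 11.5 for H3K9me3, 6.65 for TRIM28 and -18.8 for SETDB1. With the q limit on the first list alone, the change at the same 43 ARID1A peaks, in percentage points, was 0 (-17.1 to 17.1) for H3K9me3, 18.6 (1.24 to 36.0) for TRIM28 and -2.33 (-24.2 to 19.5) for SETDB1. At ARID1A sites of unmodified cells, the change at ARID1A sites, in percentage points, was -22 for H3K9me3, -0.456 for TRIM28 and -27.3 for SETDB1. With the second list alone against IgG, the change at ARID1A sites, in percentage points, was 1.35 for H3K9me3, 6.33 for TRIM28 and 4.98 for SETDB1. With the first list alone against IgG, the change at ARID1A sites, in percentage points, was -2.12 for H3K9me3, 3.93 for TRIM28 and -4.52 for SETDB1. Against the IgG control, retention at ARID1A sites minus elsewhere, in percentage points, was 14.4 for H3K9me3, 5.35 for TRIM28 and 16.8 for SETDB1. Among each list's top 10000, retention at ARID1A sites minus elsewhere, in percentage points, was 1.74 for H3K9me3, 1.43 for TRIM28 and -6.42 for SETDB1. With 50% overlap of intervals, retention at ARID1A sites minus elsewhere, in percentage points, was 3.22 for H3K9me3. After merging within 1 kb, retention at ARID1A sites minus elsewhere, in percentage points, was 3.49 for H3K9me3, 0.913 for TRIM28 and 0.359 for SETDB1. In IgG lists at q of at most 0.05, retention at ARID1A sites minus elsewhere, in percentage points, was 17.1 for H3K9me3, 5.53 for TRIM28 and 15.1 for SETDB1. With the q limit on the first list alone, retention at ARID1A sites minus elsewhere, in percentage points, was 0.509 for H3K9me3 and -2.25 for SETDB1. At ARID1A sites of unmodified cells, retention at ARID1A sites minus elsewhere, in percentage points, was 8.9 for H3K9me3, -1.04 for TRIM28 and -2.46 for SETDB1. Within deciles of fold enrichment, retention at ARID1A sites minus elsewhere, in percentage points, was 1.08 for H3K9me3 and -1.64 for SETDB1. With the second list alone against IgG, retention at ARID1A sites minus elsewhere, in percentage points, was 16 for H3K9me3, 3.63 for TRIM28 and 16 for SETDB1. With the first list alone against IgG, retention at ARID1A sites minus elsewhere, in percentage points, was 3.6 for H3K9me3, 0.51 for TRIM28 and 0.881 for SETDB1. Against the IgG control, the ratio to random lists for chromosome 19 ZNF genes was 0.92 for shARID1A H3K9me3. Among each list's top 10000, the ratio to random lists for chromosome 19 ZNF genes was 1.48 for shARID1A H3K9me3. At q of at most 0.05, the ratio to random lists for chromosome 19 ZNF genes was 1.37 for shARID1A H3K9me3. In IgG lists at q of at most 0.05, the ratio to random lists for chromosome 19 ZNF genes was 0.939 for shARID1A H3K9me3. Against the IgG control, the percentage of peaks in protein-coding genes was 48.2 for shCtrl H3K9me3 and 45.1 for shARID1A H3K9me3. With both controls required, the percentage of peaks in protein-coding genes was 50.9 for shCtrl H3K9me3 and 40.3 for shARID1A H3K9me3. At q of at most 0.05, the percentage of peaks in protein-coding genes was 57.8 for shCtrl H3K9me3 and 36.4 for shARID1A H3K9me3. In IgG lists at q of at most 0.05, the percentage of peaks in protein-coding genes was 54.6 for shCtrl H3K9me3 and 42.1 for shARID1A H3K9me3. With the second list alone against IgG, the fold of overlap over shifted positions was 0.868 for unmodified ARID1A with unmodified H3K9me3.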

Other observations

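Of 429 transfer RNA (tRNA) genes with 1000 bp on either side, 311 had a peak in shCtrl SETDB1 against input, 293 of them with a q of at most 0.05. In shARID1A SETDB1 40 had one, and in shARID1A H3K9me3 184. Against IgG the numbers lay closer, 331 in shCtrl SETDB1, 282 in shARID1A SETDB1, 328 in shARID1A H3K9me3 and 297 in shCtrl ARID1A, and no random lists were drawn for these genes. The SETDB1 list was longer in shARID1A there, with 276586 peaks against 114369 in shCtrl. Among strong peaks the SETDB1 numbers stayed apart, 307 in shCtrl and 71 in shARID1A against IgG, and 293 and 26 against input. Strong lists were of unlike length too, with 55343 and 6838 SETDB1 peaks against IgG. Among 49 ribosomal RNA genes 32 had a peak in shARID1A SETDB1, 32 in shARID1A TRIM28 and 27 in shARID1A H3K9me3 against input. In shCtrl cells the numbers were 13 for ARID1A, 5 each for SETDB1 and TRIM28 and 4 for H3K9me3, and shCtrl ARID1A had 34 against IgG, 27 of them strong. Both gene groups were chosen after the strongest peaks were seen.

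All tests of explanations below were chosen after the results were seen. Of the 835 strong peaks of the library labelled unmodified ARID1A, 79.5% met a strong peak of the library labelled shCtrl H3K9me3 and 78.0% one of shCtrl SETDB1, whereas 0.240% met one of shCtrl ARID1A. The last share could not be high, since shCtrl ARID1A had 43 strong peaks, against 6833 and 37702 in the other lists. A far larger share met a peak of the whole shCtrl ARID1A list, as given above for the q limit on the first list alone. An exchange of the ARID1A and H3K9me3 labels in shCtrl cells would put H3K9me3 in the library labelled shCtrl ARID1A, whose chromosome 19 ZNF genes stood below random lists against input (0.355 times), against IgG (0.666) and among the top 10000 peaks (0.251), where unmodified H3K9me3 stood above them (1.72, 1.83 and 1.84). These values go against an exchange but leave it open, since shARID1A H3K9me3 was not high there in each setting (1.08, 0.920 and 1.48). A single wrong label or mixed chromatin in the library labelled shCtrl H3K9me3 may account for the overlap: 5.39% of these peaks met a strong shARID1A H3K9me3 peak, but ARID1A loss is confounded with that library. Shared occupancy by ARID1A and H3K9me3 stays open too, since these peaks met the whole unmodified H3K9me3 list 6.38 times above shifted positions, no further than the TRIM28 list at 7.27, and all 3 lists share a control.

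Of the strong shARID1A H3K9me3 peaks, 53.5% met a strong shCtrl SETDB1 peak and 2.43% a strong shCtrl H3K9me3 peak. The library labelled shCtrl SETDB1 could hold an H3K9me3 precipitate, but its chromosome 19 ZNF genes stood at 0.936 times random lists, within their spread, at 1.19 (percentile 89.3) among its top 10000 peaks and at 0.918 (percentile 1.22) against IgG, with the same 2 unlike H3K9me3 references. Its ZNF genes on other chromosomes stood at 1.10 (percentile 98.8), at 1.17 (percentile 91.3) among its top 10000 peaks and at 1.07 (percentile 99.1) against IgG. That does not decide the question. Carried-over DNA would favour the tallest SETDB1 peaks, and 50.1% of the top decile by fold recurred against 9.71% of the lowest, an order that shared binding predicts as well. H3K9me3 at SETDB1 sites after ARID1A loss may also apply: 41.4% of strong shARID1A SETDB1 peaks met a strong H3K9me3 peak of the same cells, against 0.293% at shifted positions, though both lists share a control. These explanations cannot be told apart with 1 library per group.

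In shARID1A cells the ARID1A gene held 10 strong SETDB1 and 6 strong TRIM28 peaks. DNA with ARID1A sequence carried into both libraries might give such peaks, and all 6 TRIM28 peaks lay at SETDB1 peaks. Binding of TRIM28 and SETDB1 to the gene predicts the same, and all 10 SETDB1 peaks were also strong against IgG. Exon positions, which could separate these explanations, were not used here.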
